A study of Mus musculus with 1002 samples.

How the data were processed

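Single sorted cells of the mouse utricle were measured by Smart-seq2, with 1 cell in each of 1002 wells: 140 at P2, 90 Atoh1-EGFP, 88 Pou4f3-DTR and 173 wildtype wells at P4, and 95 Pou4f3-DTR and 416 wildtype wells at P6. Of these 861 were marked as passed and 141 as failed. P2, P4 Atoh1-EGFP and P4 Pou4f3-DTR cells were in sequencing pool 3, P4 wildtype in pool 7, P6 Pou4f3-DTR in pools 1 and 2, and P6 wildtype in pools 1 (162 wells), 4, 5 and 6. Age, genotype, enzyme, well volume, sequencing pool and the quality outcome of each well were taken from the labels, which describe the strain as a mix of C57BL/6 and FVB. The deposited values were expected counts per gene. Per the submitters' processing notes the tools were STAR 2.5.3a and RSEM 1.3.0 with the mm10 genome. Of the nonzero expected counts deposited by the authors, 84.6% were exactly whole, with no tolerance, and all were rounded to whole numbers before use. The gene annotation used for counting and the use of strand are not given in the sources used here. Genes with overlapping or antisense partners, and members of families with near-identical copies such as the ribosomal protein genes, are therefore uncertain, since RSEM divides shared reads among them.

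The table held 52730 entries: 52636 genes, 92 ERCC spike-ins and the entries Pou4f3DTR and exEGFP. Totals and CPM, counts scaled to a common total, were taken over genes alone. Of the genes, 52403 shared their stable identifier with GENCODE M21 on GRCm38, the assembly that mm10 names, and coordinates are from that annotation. A symbol was shared by more than 1 gene in 97 cases. No 2 cells had identical columns, and 0 columns were without a sample. Total reads per passed well ranged from 89774 to 1317136.

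The cells labelled passed were clustered with scanpy 1.11.5 and igraph 0.11.9 under Python 3.11.15, with anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Counts were scaled to 10000 per cell and log-transformed. Genes with a read in at least 3 cells, 2000 variable genes without mitochondrial or haemoglobin genes, 30 principal components, 15 neighbours and Leiden resolution 1 with seed 0 were used. A cluster was named for the class with most markers among its top 50 genes by fold, with reads in at least 25% of its cells, if at least 3 markers were found and its top 10 genes held no greater number from another class. Marker lists covered hair cells, supporting cells, non-sensory epithelium, mesenchyme, glia, melanocytes, endothelium, pericytes, immune cells, neurons and erythroid cells, with immature, type I and type II lists within hair cells. Plate wells were not put through a doublet caller. Hair-cell-like wells with reads of at least 5 supporting cell markers were counted as possibly mixed instead, 26 of 353. Of the passed cells 353 were named hair-cell-like, 191 supporting-cell-like and 233 stayed unnamed.

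Classes with at least 10 cells in both groups were compared by their summed counts as CPM, with exact Poisson 95% intervals, and shares with exact binomial (Clopper-Pearson) 95% intervals. Because no label names an animal, each group counted as 1 sample, and no test, p-value or standard error was computed. The cells of the comparisons at P6 were 54 Pou4f3-DTR and 178 wildtype hair-cell-like cells (35757892 and 91016991 reads) and 14 and 82 supporting-cell-like cells; P4 wildtype gave 64 and 38. A group under 3 counts was set to 3 counts for folds, so that folds against 0 are lower bounds by reads, not by cells, also within the medians of lists. Genes named by size were the 10 with the largest fold in each direction among genes with at least 50 CPM and reads in at least 25% of cells in the higher group, at least 2-fold, with the same direction in every comparable pool and in the mean of per-cell CPM. Gene models without a symbol, predicted genes, pseudogenes and sex-linked markers were left out of names. The genotype genes and fixed lists were named besides: hair bundle and transduction, hair cell synapse and channels, cell cycle, Notch pathway, Wnt pathway, otolith and acellular matrix, immediate early and heat shock, p53 and injury, gap junction, ion transport, ribosomal proteins and mitochondrially encoded genes. List members with at least 10 CPM in either group counted as measured, and as higher or lower from 1.5-fold. The median log2 fold of a list was set among 10000 random lists of the same size matched over 20 expression bins, as a description of these libraries.

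The samples' groups, the lists, the rule for named genes and the alternatives were chosen before the data were examined, except for 2 alternatives named with their results. Alternatives covered resolution 0.5 and 2, 1000 variable genes, cells with at least 1000 genes whatever the label, pools removed from the values, other scalings, a filter at 10 CPM and 10% of cells or none, thinning to 80000 reads per cell, single pools, and own quality filters at 1000 genes and 20% mitochondrial reads. The comparison of summed counts was tested on simulated data in which 200 genes had known folds. At a 4-fold change it recovered 98% of genes in P6 hair-cell-like and 79% in P6 supporting-cell-like cells, 92% and 84% at P4, and 97% and 87% between the ages, while at 2-fold it recovered 43 to 49%. The simulated genes had a mean of at least 50 CPM in P6 wildtype, or in P4 Atoh1-EGFP where that was the group compared against. Cells were drawn independently, without differences between pools, animals or clusters. Rates of unchanged genes passing the size filter therefore cover neither such differences nor genes lower in those groups.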

Results

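Single cells of the postnatal mouse utricle, a balance organ of the inner ear, were sorted by FACS into wells and sequenced with Smart-seq2, a full-length method without molecular identifiers. The utricle holds hair cells, the receptors of head movement, among supporting cells, with non-sensory epithelium around them. The wells, each with 1 cell, fell into 6 groups by age and genotype. At P2 there were 140 wells labelled Atoh1-EGFP;Pou4f3-DTR. At P4 there were 90 Atoh1-EGFP and 88 Pou4f3-DTR wells besides wildtype, and at P6 95 Pou4f3-DTR wells besides wildtype, the group with the most wells. Atoh1 and Pou4f3 are transcription factors of hair cells, EGFP is a green fluorescent reporter, and DTR is the receptor for diphtheria toxin, used to kill cells that carry it. Whether a toxin was given, which gates were set for sorting and which animal a cell came from are not in the labels. Each group was therefore counted as 1 sample, with no replicate, and no difference below has a test. Intervals are 95% and cover counting error only. Those of CPM count reads. PCR reads without molecular identifiers are not independent molecules, so these intervals are too narrow for molecules or cells.

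The 861 wells that the labels mark as passed held a median of 512726 reads (range 89774 to 1317136) and 3466 detected genes (range 1121 to 7249). The group medians of reads in passed wells ran from 231750 at P2 to 675966 in P4 wildtype. The share of wells that passed was 54.3% at P2 (exact binomial interval 45.7 to 62.7%), 86.7% in P4 Atoh1-EGFP (77.9 to 92.9%), 81.8% in P4 Pou4f3-DTR (72.2 to 89.2%) and 91.9% in P4 wildtype (86.8 to 95.5%). At P6, 94 of 95 Pou4f3-DTR wells and 91.8% of wildtype wells (88.8 to 94.3%) passed. In P6 wildtype the share was 86.4% in sequencing pool 1 and between 95.2% and 95.5% in pools 4, 5 and 6. The failed wells held a median of 2043 reads, and 46 of them had at least 1000 detected genes.

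The P2 cells were the only group prepared with both reverse transcriptases, maxima and smartscribe, and in 5 well volumes, so they compare the chemistries within 1 pool, age and genotype. Over all volumes more genes were detected with maxima, with a median of 3641 over 69 wells against 1768 over 71 wells with smartscribe. With 5 reads needed for detection these medians lay closer, at 1712 and 1424, and among passed wells they were 3436 and 1913. With any read counted, the medians among passed wells were 4620 for maxima and 2334 for smartscribe. With every passed well thinned to 80000 reads they were 4041 and 2149, at median depths of 280298 and 201559 reads before thinning. The intervals of the share of wells that passed overlapped, at 47.8% for maxima (35.6 to 60.2%) and 60.6% for smartscribe (48.3 to 71.97%). By volume, the share labelled as passed ran from 39.3% at volume 3 to 66.7% at volume 1. With a filter of 1000 genes in place of the label it was highest at volumes 2 and 3 (89.3% each) and lowest at volume 0.5 (57.1%), so the order of volumes depended on the filter. Among wells labelled as passed, the median of genes with maxima ran from 4230.5 at volume 0.5 to 5112 at volume 3. The labels give no unit for the volume. Over passed and failed wells together the order was the other way at volume 0.5, with a median of 10.5 genes for maxima and 1675 for smartscribe, while at volume 4 it was 2278 and 1710.

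**Figure D1:**
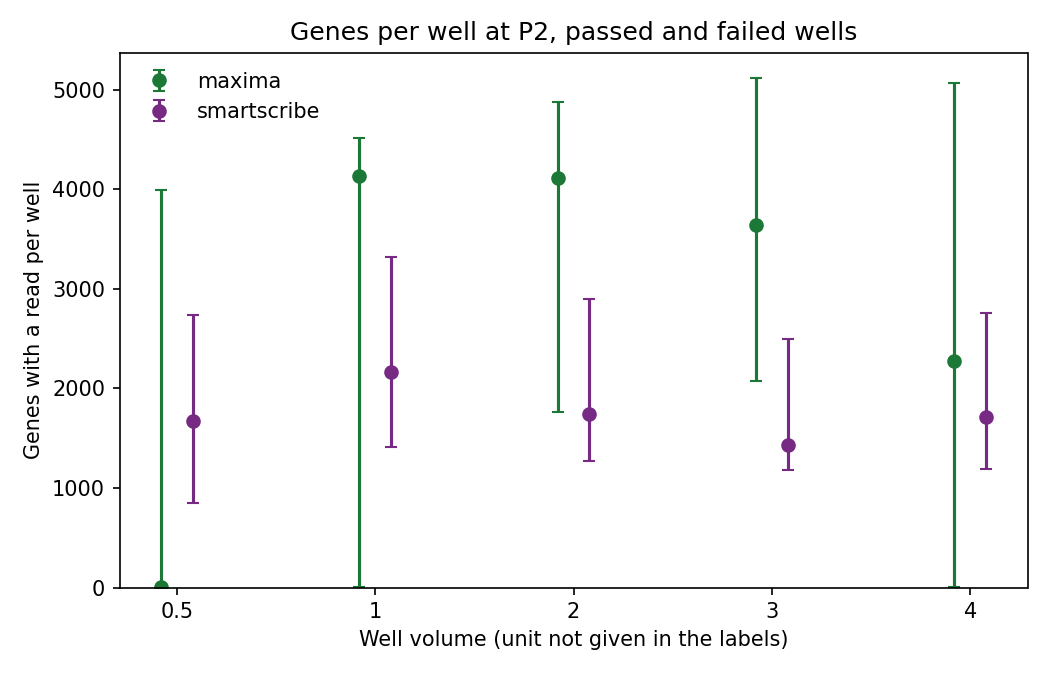
Genes detected per P2 well, passed and failed (vertical axis) by well volume, whose unit the labels do not give (horizontal axis), for each enzyme. Points are medians and bars run from the lower to the upper quartile; the maxima medians lie between 10.5 and 4133 and the smartscribe medians between 1429 and 2165.5.

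Clustering of the passed cells gave 13 clusters. Hair-cell-like cells, with markers such as Otof, Ptprq, Espn and Ccer2, made up 5 clusters, and supporting-cell-like cells, with Sparcl1, Otog, Jag1 and Slc1a3, made up 2 clusters. Cells like non-sensory epithelium (58 cells, with Oc90, Slc26a4 and Wfdc2) and mesenchyme-like cells (26 cells, with Otor, Coch and Col1a2) formed a cluster each. The other 4 clusters, with fewer than 3 detected markers of any class, stayed unnamed. They made up 14.5% of passed cells at P2, 12.8% in P4 Atoh1-EGFP, 19.4% in P4 Pou4f3-DTR, 33.96% in P4 wildtype, 25.5% in P6 Pou4f3-DTR and 31.4% in P6 wildtype.

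Hair-cell-like cells were 57.4% of P6 Pou4f3-DTR cells (54 of 94, interval 46.8 to 67.6%) and 46.6% of P6 wildtype cells (41.5 to 51.7%). Supporting-cell-like cells were 14.9% (8.39 to 23.7%) and 21.5% (17.5 to 25.9%). Both pairs of intervals overlapped. Within pool 1, which held both genotypes, the hair-cell-like cells were 33 of 60 Pou4f3-DTR cells and 42.1% of wildtype cells, and the supporting-cell-like shares were 13.3% and 19.3%. The hair-cell-like share of P6 wildtype ranged from 40.5% in pool 6 to 55.95% in pool 4. At P4 hair-cell-like cells were 24.4% of Atoh1-EGFP cells (15.3 to 35.4%), 19.4% of Pou4f3-DTR cells (11.1 to 30.5%) and 40.3% of wildtype cells (32.6 to 48.3%), and at P2 they were 31.6% (21.4 to 43.3%). Cells like non-sensory epithelium were 15.8% of P2, 30.8% of P4 Atoh1-EGFP and 26.4% of P4 Pou4f3-DTR cells, but 1.26% of P4 wildtype and 0 P6 wildtype cells, which allows up to 0.961% by the exact interval. This contrast depended on the clustering. With enzyme centred out they were 19.5% of P4 wildtype and 17.5% of P6 wildtype cells, against 25.6% of P4 Atoh1-EGFP and 19.4% of P4 Pou4f3-DTR cells. At P2 they were then 10.5%, below both wildtype groups. Mesenchyme-like cells were 19.7% of P2 cells (11.5 to 30.5%) and at most 5.56% of any group at P4 or P6. At resolution 0.5 no cluster was named mesenchyme, so that 0 of 76 P2 cells were. In the other alternative clusterings the P2 share ran from 16.3% to 18.4%. The sort gates can set all of these shares. Enzyme can too, since the 4 clusters numbered 7, 8, 9 and 12 held 0 smartscribe cells.

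**Figure D2:**
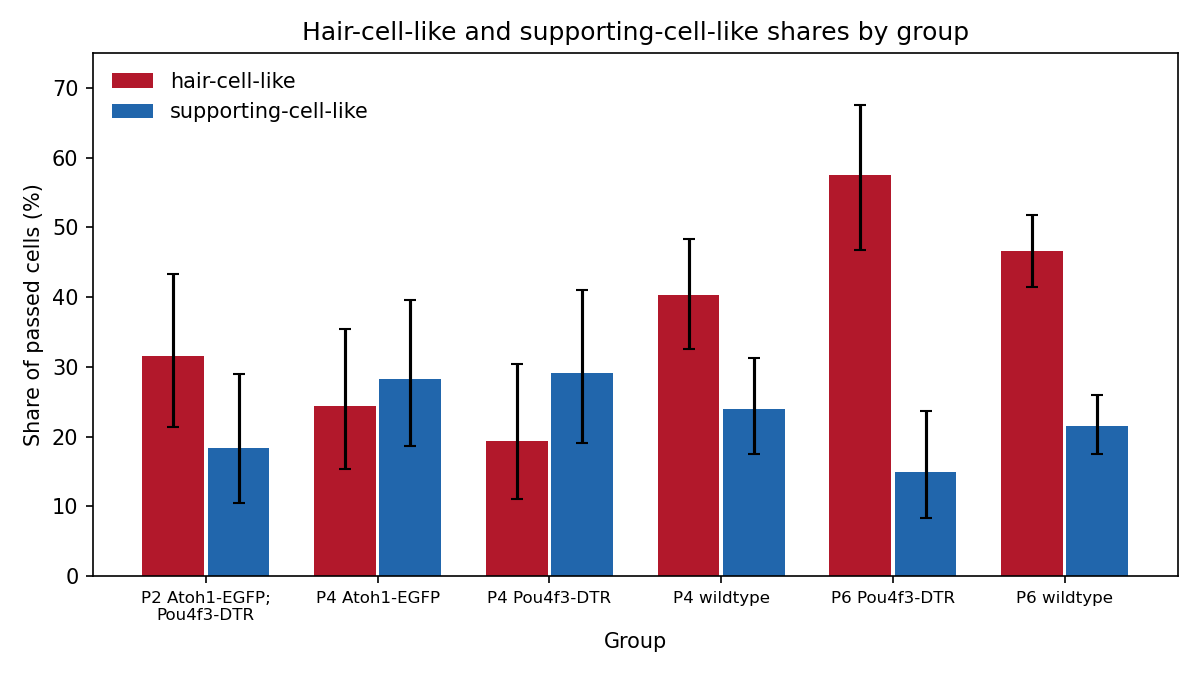
Share of passed cells, in percent (vertical axis), that was hair-cell-like or supporting-cell-like in each of the 6 groups (horizontal axis). Error bars are exact 95% binomial intervals; the hair-cell-like share runs from 19.4% in P4 Pou4f3-DTR to 57.4% in P6 Pou4f3-DTR.

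Pou4f3 (ENSMUSG00000024497.3, chromosome 18, 42394539 to 42397249 in GRCm38), which the genotypes name, was read in hair-cell-like cells of every group. Its summed level was 1187 CPM (read counts scaled to the same total in every group) at P2, 1031 in P4 Atoh1-EGFP, 706 in P4 Pou4f3-DTR, 1296 in P4 wildtype, 661 in P6 Pou4f3-DTR and 905 in P6 wildtype. Among P6 hair-cell-like cells 47 of 54 Pou4f3-DTR cells and 92.1% of wildtype cells held a Pou4f3 read. In P6 supporting-cell-like cells Pou4f3 stood at 0 CPM in Pou4f3-DTR and 13.5 CPM in wildtype. By pool the P6 hair-cell-like levels of Pou4f3 were 549 and 791 CPM in Pou4f3-DTR pools 1 and 2, and 708, 701, 1074 and 1153 CPM in wildtype pools 1, 4, 5 and 6. Atoh1 (ENSMUSG00000073043.5, chromosome 6, 64729125 to 64731245), the factor that starts hair cell differentiation, stood at 589 CPM in P4 wildtype hair-cell-like cells. It was lower in the other groups, at 138.9 CPM at P2, 205.9 in P4 Atoh1-EGFP, 192.2 in P4 Pou4f3-DTR, 249.7 in P6 wildtype and 51.4 in P6 Pou4f3-DTR. P4 wildtype cells were made with maxima in pool 7. P4 Atoh1-EGFP and P4 Pou4f3-DTR cells were made with smartscribe in pool 3, and P2 cells with both enzymes in pool 3. Differences of Pou4f3 and Atoh1 between P4 wildtype and the groups of pool 3 can therefore not be told apart from enzyme and pool. Those between P2 and the P4 groups of pool 3 are mixed with enzyme. P4 Atoh1-EGFP and P4 Pou4f3-DTR shared both enzyme and pool.

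The table also carried 2 entries outside the mouse genome, named Pou4f3DTR and exEGFP. Pou4f3DTR reads were rare, with 78 reads in 39 wells. In P6 Pou4f3-DTR, 10 of 61 wells of pool 1 held such a read (16.4%, 8.15 to 28.1%) and 10 of 34 wells of pool 2 (29.4%, 15.1 to 47.5%). All 20 of these wells were hair-cell-like. Among P6 cells labelled wildtype, 0 wells of pool 1 held a Pou4f3DTR read, which allows up to 2.25% by the exact interval, while 2 of 88 wells in pool 4, 7 of 83 in pool 5 and 10 of 83 in pool 6 did. No such read was found in 88 P4 Pou4f3-DTR or 140 P2 wells, nor in P4 Atoh1-EGFP or P4 wildtype, and exEGFP had 0 reads in every group. This entry therefore did not separate the labelled genotypes at P2 or P4, and the genotypes below are as labelled.

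The P6 groups shared enzyme and well volume and compare cells labelled Pou4f3-DTR with cells labelled wildtype. Within pool 1 wells of both genotypes carried the same plate positions, so they cannot all have shared a plate. Differences between plates were not told apart from genotype. In hair-cell-like cells (54 labelled Pou4f3-DTR) genes of the immature hair cell list were lower in Pou4f3-DTR. Atoh1 stood at 51.4 CPM, with a read in 5 of 54 cells, against 249.7 CPM in 33.1% of wildtype cells. Hes6 (38.1 against 105.6 CPM), the Notch ligand gene Dll1 (25.2 against 105.2) and the Notch modifier gene Mfng (26.8 against 63.8) were also lower. Of the 8 measured members of the immature hair cell list, 7 were at least 1.5-fold lower and 0 higher, with a median log2 fold of -1.70 for Pou4f3-DTR over wildtype (percentile 0 among 10000 random lists matched on expression) and of -1.25 within pool 1. That list had been fixed only to name clusters, and its use between groups was chosen after its values were seen. Most Pou4f3-DTR cells lay in clusters 1, 11 and 12, and most wildtype cells in clusters 9, 12 and 1. Cluster 11 is led by Ocm, read in 36 of its 37 cells, and Calb1, and clusters 4 and 12 carry the immature markers.

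**Figure D3:**
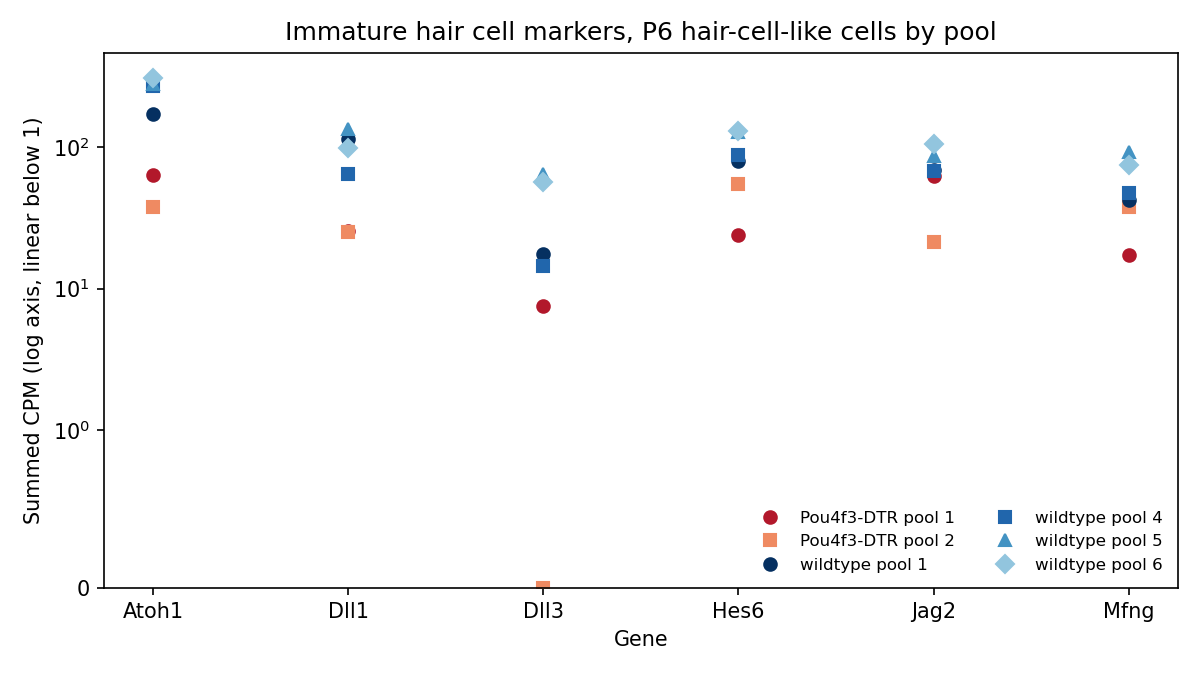
Summed level in CPM (logarithmic axis) of immature hair cell markers in P6 hair-cell-like cells, with a point for each sequencing pool of Pou4f3-DTR and of cells labelled wildtype; a level of 0 is drawn at the foot of the axis. Atoh1 stands at 63.6 and 37.4 CPM in the Pou4f3-DTR pools and between 169.9 and 304.5 CPM in the wildtype pools.

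Among genes named by size in these P6 hair-cell-like cells, Car8 was higher in Pou4f3-DTR, at 142.04 CPM with reads in 18 of 54 cells, against 14.3 CPM in 7.87% of wildtype cells (log2 fold 3.31). Car8 encodes a carbonic anhydrase relative (ENSMUSG00000041261.9, chromosome 4, 8143362 to 8239041). The calcium-binding Calb1 (ENSMUSG00000028222.2, chromosome 4, 15881264 to 15908064) stood at 429 against 65.9 CPM and Ocm (ENSMUSG00000029618.13, chromosome 5, 144019804 to 144026670) at 747 against 145.95 CPM. Nadk2, Lce6a, Nipal1, Depdc7, mt-Nd4, Prorsd1 and Crebrf made up the rest of the 10 higher genes, with log2 folds from 1.95 to 2.81. Calb1, Ocm and Lce6a were also among the leading genes of cluster 11. That cluster held 15 of the 54 Pou4f3-DTR cells and 16 wildtype cells, a smaller share of the larger wildtype group. For these genes a different mix of clusters was not told apart from a change within cells, as no single gene was weighted by cluster. The 10 lower genes were Ablim3, an actin-binding LIM protein gene (ENSMUSG00000032735.14, chromosome 18, 61799392 to 61911824; 2.71 CPM, interval 2.20 to 3.31, against 70.01, log2 fold -4.69), Cggbp1, Midn, the splicing factor Cwc22, Krt23, Dyrk1b, Hivep2, Ralgps1, Gmfb and Rint1, the last at -2.73. Within pool 1 the log2 fold of Car8 was 4.37, of Calb1 3.63, of Ocm 3.43, of Ablim3 -3.28 and of Cwc22 -4.77. Cwc22 ranged widely among wildtype pools, at 221.4, 495, 21.1 and 42.5 CPM in pools 1, 4, 5 and 6. In simulated data for this comparison 2.57% of 4008 unchanged genes passed the size filter. That rate covers only genes with a mean of at least 50 CPM in wildtype, and no differences between pools were simulated. With the expression filter lowered 0 of these 20 genes were named again, since rarer genes with larger folds then took the places.

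In the P6 hair-cell-like cells, of 20 hair bundle and transduction genes, 8 were lower in Pou4f3-DTR and 0 higher, among them Espn (370.3 against 679 CPM), Myo15 (507 against 832), Cdh23 (131.5 against 237.6) and the transduction channel gene Tmc2 (20.8 against 79.9). Their median log2 fold was -0.44 (percentile 0.61) and -0.11 within pool 1. Of 12 synapse and channel genes 4 were lower, including Otof, needed for transmitter release (909.7 against 2169 CPM), and 1 higher, with a median of -0.17 (percentile 25.9) that was 0.034 within pool 1 and 0.29 against wildtype of pool 1 alone. Of 11 Notch pathway genes 5 were lower, namely Dll1, Dll3, Hes6, Mfng and Jag2, and Notch1 was higher (42.1 against 8.68 CPM), with a median of -0.52 (percentile 20.25) and of -1.07 within pool 1. All 14 measured mitochondrially encoded genes were higher, with a median of 1.48 and of 1.32 within pool 1; mt-Co1 stood at 5356 against 2695 CPM and mt-Rnr2 at 20135 against 9605 CPM. The median mitochondrial share of reads over all passed cells was 3.45% and 4.47% in the Pou4f3-DTR pools, and 2.40%, 3.44%, 1.23% and 1.20% in wildtype pools 1, 4, 5 and 6.

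In the hair-cell-like cells at P6, 6 of 8 otolith and acellular matrix genes were higher in Pou4f3-DTR and 1 lower (median log2 fold 1.38, percentile 100, and 2.14 within pool 1), with Otog at 359.1 against 76.3 CPM, Otoa at 127.4 against 36.6 and Sparcl1 at 202.6 against 76.6. Few cells carried these reads, as Otog was read in 12 of 54 Pou4f3-DTR cells and 10.1% of wildtype cells. Of 11 supporting cell markers 7 were higher and 2 lower (median 1.29). Hair-cell-like wells with reads of at least 5 supporting cell markers were 8 of 54 in Pou4f3-DTR (14.8%, 6.62 to 27.1%) and 9 in wildtype (5.06%, 2.34 to 9.38%). Of 6 ion transport genes 3 were higher and 1 lower, with a median of 2.20 that was -0.26 within pool 1. Kcnj16, a potassium channel gene, stood at 58.3 against 3.45 CPM. Of 21 hair cell markers 2 were higher and 8 lower (median -0.45), of 6 type I markers 3 higher and 0 lower (0.85), and of 4 type II markers 1 higher and 2 lower (-0.53).

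In the same cells, of 13 immediate early and heat shock genes 4 were higher and 4 lower (median log2 fold -0.35, but 0.11 within pool 1 and 0.57 against wildtype of pool 1 alone), and of 8 p53 and injury genes 1 was higher and 4 lower (-0.49), with Cdkn1a, a cell cycle inhibitor, at 66.1 against 122.97 CPM. Of 5 Wnt pathway genes 2 were higher and 2 lower (-0.020, but -0.83 within pool 1 and 0.83 for Pou4f3-DTR pool 2), and of 5 cell cycle genes 0 were higher and 2 lower (-0.17, but 0.60 within pool 1 and -1.10 for Pou4f3-DTR pool 2). Of 80 ribosomal protein genes 74 stayed within 1.5-fold (-0.12, and -0.60 within pool 1). Of 6 non-sensory epithelium markers 3 were higher and 2 lower (0.16), and of 3 neuron markers 0 were higher and 1 lower (-0.31). Of the gap junction, glia and immune lists 1 member each was measured, and of the mesenchyme, melanocyte, endothelium, pericyte and erythroid lists 0.

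In supporting-cell-like cells at P6 (14 Pou4f3-DTR against 82 wildtype, in clusters 3 and 7, most of them in 3 in both groups) mitochondrially encoded genes were again higher in Pou4f3-DTR. All 14 measured were higher, with a median log2 fold of 1.29; mt-Cytb stood at 6909 against 2804 CPM. Of 14 Notch pathway genes 7 were lower and 1 higher (median -0.71, percentile 6.22). The receptor Notch1 stood at 301.7 against 586 CPM and its target Heyl at 67.1 against 210.03. Hes5 stood at 0 against 63.6 CPM, with an upper limit of 0.474 that counts reads, not cells. Only 8 of 82 wildtype cells held a Hes5 read. Hey2 was higher (133.1 against 40.98 CPM). Of 8 Wnt pathway genes 5 were lower and 1 higher (median -0.85, percentile 12.6); Lgr6 stood at 64.1 against 134.7 CPM and Lgr5 at 11.3 CPM in 1 of 14 cells against 91.6 CPM in 14 of 82. Of 13 immediate early genes 2 were higher, Btg2 among them (3942 against 1735 CPM), and 4 lower, Junb among them (846 against 1683). Of 10 otolith genes 0 were higher and 2 lower, with Otogl at 206.2 against 466 CPM, and of 8 ion transport genes 5 were higher and 3 lower.

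The genes named by size in these P6 supporting-cell-like cells rest on few cells. Arl5a, a small GTPase gene (ENSMUSG00000036093.7, chromosome 2, 52397951 to 52424901), stood at 316.4 CPM in 4 of 14 Pou4f3-DTR cells against 0.0951 CPM in 1 of 82 wildtype cells. Kncn, Dcaf12l1, Rfwd2, Psip1, Flrt1, Mast3, Dlx1, Ppp2r5e and Alg14 were the other higher genes, with Psip1 at 185.2 against 9.39 CPM. Of the 10 lower genes 9 had 0 reads in the 14 cells: Copb2, Tcaf1, Dhrs1, Cyfip1, Nde1, B3gnt2, F2r, Plcd1 and Tvp23b, and Pik3r2 was the tenth. Copb2, a coat protein gene of vesicles (ENSMUSG00000032458.6, chromosome 9, 98563721 to 98588382), stood at 184.1 CPM in 34 of 82 wildtype cells and was read in 0 of 14 Pou4f3-DTR cells. Its fold of 478 against a floor of 3 counts over the group rests on reads, which are not independent molecules. It is no lower bound by cells. In simulated data for this comparison 24.8% of 3546 unchanged genes, all with a mean of at least 50 CPM in wildtype, passed the size filter. Neither pool held 10 of the Pou4f3-DTR cells, and no list could be compared within a pool.

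At P4 the Pou4f3-DTR and Atoh1-EGFP groups shared pool 3, the smartscribe enzyme and the well volume. Wells of both groups carried the same plate positions, so they cannot all have shared a plate. Differences between plates were not told apart from genotype. In hair-cell-like cells (14 against 19, in clusters 1 and 4 for the most part) immediate early genes, which respond to stimulation and stress, were higher in Pou4f3-DTR: 9 of 14 were higher and 2, Hspa1a and Hspa1b, lower (median log2 fold 0.88, percentile 100). Atf3 (ENSMUSG00000026628.13, chromosome 1, 191170296 to 191218039) stood at 167.4 CPM in 5 of 14 cells against 2.43 CPM in 1 of 19, Fos at 1327 against 854 CPM, Egr1 at 407.4 against 240.6 and Ier2 at 171.4 against 39.3. Adam11, Amotl1, Efhd2, Ift80, Dupd1, Cpz, Lrrc28, Cyr61 (250.7 against 21.7 CPM) and the nuclear receptor gene Nr4a1 (236.4 against 11.9) were the other higher genes. Naa16, Cdkl1, Ell3, Zfp426, Slc12a7, Zc2hc1c, Gzf1, Asic3, Dimt1 and Usp1 were lower, with Cdkl1 at 0 against 70.1 CPM. Of 20 hair bundle genes 8 were higher and 5 lower (0.22), of 13 synapse genes 1 higher and 5 lower (-0.45), with Slc17a8, the glutamate loader of synaptic vesicles, at 165.2 against 366.6 CPM. Of 9 Notch pathway genes 6 were higher and 1 lower (0.91), with Dll3 at 90.3 against 41.3 CPM. Of 7 otolith genes 5 were higher and 1 lower (1.51), with Otog read in 1 of 14 cells, and 5 of 7 supporting cell markers were higher; wells with at least 5 such markers were 2 of 14 and 0 of 19. The median gene of this comparison lay at -0.11 (2372 genes), and the list medians above lie outside the range from that to 0. Of unchanged simulated genes 11.6% passed its size filter, and 3 of its 20 genes were named again with the filter lowered.

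In supporting-cell-like cells at P4 (21 Pou4f3-DTR against 22 Atoh1-EGFP, all in cluster 3) 7 of 13 Notch pathway genes were lower in Pou4f3-DTR and 3 higher (median log2 fold -0.77, percentile 1.17). Hey1 stood at 92.2 against 257.7 CPM, the ligand gene Jag1 at 89.05 against 174.7 and Hes5 at 34.7 against 72.6. Of 10 Wnt pathway genes 4 were higher and 2 lower (0.41), with Lgr5 at 152.9 against 42.6 CPM. All 5 measured cell cycle genes were lower, with Pcna at 25.1 against 111.9 CPM. Of 6 non-sensory epithelium markers 4 were lower and 1 higher (-1.12), with Oc90, an otolith protein gene, at 155.2 against 655 CPM, and of 4 glia markers 3 were higher and 0 lower (1.10). Nedd9, an adhesion scaffold gene (ENSMUSG00000021365.15, chromosome 13, 41309581 to 41487362), stood at 165.7 CPM in 14 of 21 cells against 5.55 CPM in 6 of 22, and Lats1, a Hippo pathway kinase gene, at 50.2 against 3.94 CPM. Zfp281, Insr, Zfp868, Enpp4, Nhlrc2, Kpna2, Mier3 and Ppp1cb were the other higher genes. Dolpp1, Pou3f2, Bmp1 (2.80 against 64.9 CPM), Stoml1, Plscr2, Rad1, Plxdc2, Prpf40b, Tspan4 and Rab40c were lower. Of unchanged simulated genes 13.5% passed the size filter here, and 0 of these 20 genes were named again with the filter lowered.

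Wildtype cells of P4 and P6 compare ages with the same enzyme and volume, but P4 was pool 7 alone and P6 pools 1, 4, 5 and 6, so age and pool cannot be told apart. In hair-cell-like cells (64 at P4, most in clusters 12, 9 and 1 at both ages) 4 of 8 immature markers were higher at P4 and 1 lower (median log2 fold 0.56 for P4 over P6), with Atoh1 at 589 against 249.7 CPM and Gadd45g at 708 against 470.4. Of 12 synapse and channel genes 4 were lower at P4 and 1 higher (-0.38, percentile 0.07, but 0.13 against P6 pool 1), with the acetylcholine receptor gene Chrna9 at 129.9 against 276.1 CPM and Slc17a8 at 82.7 against 139.6. Of 6 type I markers 3 were lower and 0 higher (-0.49), of 20 hair bundle genes 1 higher and 2 lower (0.14), and of 11 Notch pathway genes 5 higher and 3 lower (0.53). Of 9 otolith genes 7 were higher at P4 (0.95), but the median was -0.019 against P6 pool 4 and -0.55 with finer clusters, and 9 of 13 supporting cell markers were higher with them. Of 14 mitochondrially encoded genes 11 were lower (-0.76), but the median was 0.057 against pool 5 and 0.25 against pool 6.

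By size, the P4 hair-cell-like cells of wildtype were higher in Npc2, a cholesterol carrier of the lysosome (ENSMUSG00000021242.9, chromosome 12, 84754562 to 84773152; 50.9 against 11.7 CPM), and in Snd1, Cst3, Anks1, Mxd4, Qtrt1, Epb41l4a, Arf2 and Tab1. They were lower in the kinesin gene Kif13a (ENSMUSG00000021375.10, chromosome 13, 46749087 to 46929867; 2.98 CPM in 8 of 64 cells against 73.8 CPM in 26.4% of P6 cells), in Cwc22, Man2a2, Far1, Rdx, which encodes the actin linker radixin (18.4 against 71.7 CPM), Phactr2, Scai, Trp53inp1, Epha1 and Foxj3. The log2 fold of Cst3 was 1.73 but -0.031 with finer clusters, and that of Cwc22 was -3.25 but -0.12 against pool 5. Of unchanged simulated genes, all with a mean of at least 50 CPM at P6, 1.35% passed the size filter. Of the 20 genes selected by size, not all given here, 1 was named again with the filter lowered.

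In supporting-cell-like cells of wildtype (38 at P4 against 82 at P6, most in cluster 3) Oc90 (ENSMUSG00000015001.17, chromosome 15, 65876053 to 65912397) was higher at P4, at 4582 CPM in 23 of 38 cells against 329.1 CPM in 21 of 82 (log2 fold 3.80). Of 8 non-sensory epithelium markers 6 were higher at P4 and 0 lower (median 0.94, percentile 99.1), with the potassium channel gene Kcnq1 at 94.6 against 39.1 CPM. Of 13 immediate early genes 5 were higher and 0 lower (0.51), with Jun at 3674 against 1339.9 CPM. The cell cycle regulator Ccnd1 stood at 248.5 against 114.9 CPM and Lgr5 at 12.4 against 91.6, within a Wnt pathway list with 5 of 10 higher and 3 lower (0.61). Hes5 stood at 259.3 against 63.6 CPM, within a Notch pathway list with 3 of 15 higher and 4 lower (-0.026, but 0.27 to 0.41 against each P6 pool alone). Of 14 mitochondrially encoded genes 7 were lower (-0.61, but 0.12 against pool 5). Zfp467, Aifm1, Zswim8, Birc2, Mtmr4, Pole3, Ltbp4 (141.4 against 20.3 CPM), Kctd3 and Btbd3 were the other higher genes, and Cyth1, Osbpl11, Coa5, Dst, March6, Nectin3, Gadd45g, Cspp1, Lhfpl2 and Cpa6 the lower ones. Of unchanged simulated genes 10.7% passed the size filter, and 1 of these 20 genes was named again with the filter lowered.

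Fixed lists were also compared in 2 settings where genotype or age went with other differences. P4 Pou4f3-DTR and P4 wildtype differed in pool and enzyme as well, which cannot be told apart from genotype, and the median gene lay at a log2 fold of -0.39 in hair-cell-like and -0.47 in supporting-cell-like cells. Ribosomal protein genes were lower than that, at a median of -1.06 in hair-cell-like cells (14 against 64, with 59 of 80 lower) and -1.35 in supporting-cell-like cells (21 against 38, with 64 of 80 lower). The mix of clusters differed too. Of the wildtype hair-cell-like cells 23 lay in cluster 9 and 26 in cluster 12, and of the supporting-cell-like cells 8 in cluster 7. These clusters held no P4 Pou4f3-DTR cell. Mitochondrially encoded genes were higher, at 2.44 and 1.72, with mt-Co1 at 11785 against 2196 CPM in hair-cell-like cells. In supporting-cell-like cells 10 of 14 Notch pathway genes were lower (-1.59), with Hes5 at 34.7 against 259.3 CPM, and 8 of 8 non-sensory epithelium markers (-1.97). The P2 cells made with smartscribe differed from P4 Atoh1-EGFP in age, genotype and well volume together. In their hair-cell-like cells (12 against 19) 7 of 13 synapse genes were lower at P2 and 0 higher (-0.66), with Slc17a8 at 91.6 against 366.6 CPM. Of 12 immediate early genes 7 were lower and 1 higher (-1.15), and of 6 cell cycle genes 5 were higher and 0 lower (1.19), with Mcm6, a replication helicase gene, at 129.4 against 52.5 CPM.

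The 5 hair-cell-like clusters differed in the lists fixed to describe them, as summed CPM. Immature markers summed to 2098 in cluster 4 and 2859 in cluster 12, against 247.1 to 383.8 in clusters 1, 9 and 11. Type I markers summed to 42875 in cluster 1, 22749 in cluster 9 and 13749 in cluster 11, most of it from Spp1, and to 297.4 and 356.2 in clusters 4 and 12. Type II markers summed to 1383, 1070 and 1168 in clusters 4, 12 and 11, and to 255.3 and 334.4 in clusters 1 and 9. Single genes carried these sums, with Anxa4 at 1139 in cluster 4 and 711 in cluster 12 and Calb1 at 1041 in cluster 11, so the type II list did not order the clusters. Hair bundle genes summed to between 4412 in cluster 4 and 8587 in cluster 9, of which Ptprq made up 715 and 4148. By the median of that list the order was another, from 136.2 in cluster 9 and 140.2 in cluster 4 to 176.1 in cluster 12, and by sum synapse genes ran from 1641 in cluster 4 to 6963 in cluster 9. Clusters 9 and 12 held no smartscribe cells. Among the 27 cells of cluster 4 were 6 P2, 9 P4 Atoh1-EGFP and 6 P4 Pou4f3-DTR cells made with smartscribe. Enzyme can therefore not be told apart from the differences between cluster 4 and clusters 9 and 12. The immunoglobulin gene Ighm was among the leading genes of clusters 1 and 11, and the immediate early genes Btg2 and Ier2 among those of cluster 12.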

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

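All tests of the Pou4f3DTR reads were chosen after the result was seen. Reads of the Pou4f3DTR entry, which no comparison used, appeared in wells labelled P6 wildtype: 2 of 88 wells in pool 4, 7 of 83 in pool 5 and 10 of 83 in pool 6. They stand out because wildtype cells should lack this transgene, and no well of P6 wildtype pool 1 or of P4 wildtype held such a read, although 61 Pou4f3-DTR wells with 24 such reads shared pool 1. Pools 4 to 6 hold no well labelled Pou4f3-DTR. Among failed wells 0 of 4 in pool 4, 3 of 4 in pool 5 and 2 of 4 in pool 6 held such reads, against 4 of 79 and 8 of 79 passed wells in the last 2 pools; in pool 6 it was 6 reads in 35059 against 13 in 56947846.

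Reads of the endogenous Pou4f3 gene are argued against as the source: at the rate of pools 4 to 6, with 22 Pou4f3DTR reads beside 63100 Pou4f3 reads, 27.5 reads were due in the passed wildtype cells of P6 pool 1 and of P4, which held 78885 Pou4f3 reads, and 0 were found. That all of pool 4 were Pou4f3-DTR cells under a wildtype label is argued against too. Of its hair-cell-like cells 4.26% held such a read (2 of 47, upper limit 14.5%). The lower limits in the pools labelled Pou4f3-DTR were 15.6% and 25.7%. These shares take no account of depth. By them pool 5 (7.50%, 3 of 40, 1.57 to 20.4%) and pool 6 (12.5%, 4 of 32, 3.51 to 28.99%) stay open. By reads, the hair-cell-like cells of pools 4, 5 and 6 held 3 in 18953066, 3 in 24084039 and 7 in 20773722. Those of the labelled pools held 24 in 19144656 and 23 in 16613236. Pools 5 and 6 thus both held fewer such reads among more reads in all. By reads, each being Pou4f3-DTR as a whole is argued against, though reads are not independent molecules. The shares of cells do not decide it for either pool. Stray reads from wells of other pools stay open. The 0 in wildtype wells of pool 1 cannot decide, since the Pou4f3-DTR wells of that pool held only 24 such reads to stray. Some mislabelled cells stay open too. The reads in 2 failed wells of pool 6 speak against these but do not decide. Of the 2, the cell types did not decide either: 64.3% of the passed wells with such a read were hair-cell-like (9 of 14, 35.1 to 87.2%), an interval that holds the 49.2% of all passed cells there, while it was 20 of 20 in cells labelled Pou4f3-DTR (lower limit 83.2%). The absence of Pou4f3DTR reads in P2 and P4 cells labelled with the transgene stays open, and no biological explanation was tested.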

How the results depend on the processing

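The alternatives added after the data were seen were clusters with enzyme centred out and the P6 comparison with wildtype cells of pool 1 alone. No paired analysis was possible because no result comes from a test and replicate numbers only follow the order of accessions. Hair-cell-like and supporting-cell-like shares stayed within their intervals in 81 values and moved in 3; those of other classes stayed in 39 and moved in 45. The 3 were in P6 wildtype, whose hair-cell-like share was 55.95% in pool 4 alone and 40.5% in pool 6 alone against 46.6%, and whose supporting-cell-like share was 29.1% in pool 6 alone against 21.5%. The causes were not tested. The passed share at P2 was 74.3% under both own filters against 54.3%, for a cause not tested. The median of genes in P2 maxima wells was 1712 with 5 reads needed for detection, 10.5 at volume 0.5 and 2278 at volume 4, against 3641; the cause of the values by volume was not tested. Of the 20 genes named per comparison, with the filter at 10 CPM and without any filter alike, 0 were named again in P6 hair-cell-like, 11 in P6 supporting-cell-like, 3 in P4 hair-cell-like and 0 in P4 supporting-cell-like cells. Between the ages it was 1 and 0 in hair-cell-like and 1 and 1 in supporting-cell-like cells, because rarer genes then took the places by construction. Direction turned, for causes not tested, in ion transport genes of P6 hair-cell-like cells within pool 1 (-0.26 against 2.20). Between the ages in hair-cell-like cells it turned in otolith genes at resolution 2 (-0.55) and against pool 4 (-0.019; 0.95 as reported), in Cst3 at resolution 2 (-0.031 against 1.73), and in mitochondrially encoded genes against pool 5 (0.057) and pool 6 (0.25; -0.76 as reported). In supporting-cell-like cells it turned in the last list against pool 5 (0.12 against -0.61). A list median counted as turned only if it was at least 1.5-fold as reported. So counted, list medians kept their value to within 1.5-fold in 423 cases, moved in 35 and turned in 6, and of the medians reported as under 1.5-fold 48 changed sign. Single genes kept their value to within 2-fold in 747 cases, moved in 92 and turned in 1. These were the genes named by size, so in settings that the naming rule used their direction could not turn. With wildtype of pool 1 alone the log2 folds at P6 were 4.93 for Car8, 3.64 for Ocm and -3.91 for Ablim3. Pseudocounts and filters for TPM or FPKM were not run, as the values are counts, nor single pools at P4, where pool 3 held both groups, or the Pou4f3-DTR pools for supporting-cell-like cells, which held 8 and 6 cells. The number of the 20 named genes that were at least 2-fold stayed within its bound, a ratio of 1.5, in all 42 values. These genes were chosen for the largest folds in the same cells. Their direction in comparable pools and in the mean of per-cell CPM was part of the naming rule. This count could therefore hardly move, and nothing is drawn from it. Few cells limit single genes: with 14 against 82 cells, 24.8% of unchanged simulated genes passed the size filter.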

Other observations

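The test of pools for the Notch list, those of pools, depth and cluster mix for the immature list, and the test of clusters within P2 were chosen after the result was seen. Non-sensory-epithelium-like cells at P4 (19 Pou4f3-DTR against 24 Atoh1-EGFP, in pool 3) carried cell cycle reads in few cells. Of 8 measured cell cycle genes 7 were higher in Pou4f3-DTR and 0 lower, with a median log2 fold of 4.17. Cdk1, the kinase that drives mitosis, stood at 61.5 CPM in 2 of 19 cells against 7.25 CPM in 2 of 24, Birc5 at 28.4 CPM in 3 of 19 cells against 0, and the replication helicase gene Mcm6 at 36.1 CPM in 7 of 19 against 14.3 CPM in 5 of 24. Of 6 Notch pathway genes 4 were lower and 0 higher (-0.71), and of 3 gap junction genes 2 were higher and 0 lower (1.95). Apart from these, the 9 cells of cluster 10 were led by the mitotic genes Cdk1, Ube2c, Ccnb1 and Top2a, with a median of 660300 reads.

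Reads of other tissues were found in P2 hair-cell-like cells made with smartscribe. The haemoglobin gene Hba-a1 stood at 2817 CPM, from 1 of 12 cells, against 0 CPM in 19 P4 Atoh1-EGFP cells, and all 4 measured erythroid and 3 measured mesenchyme markers were higher at P2. Cwc22, one of the genes lower in P6 Pou4f3-DTR hair-cell-like cells, stood at 8.10 and 28.2 CPM in the Pou4f3-DTR pools and at 221.4, 495, 21.1 and 42.5 CPM in P6 wildtype pools 1, 4, 5 and 6.

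Immature hair cell markers, several Notch ligands among them, were lower in P6 Pou4f3-DTR hair-cell-like cells, with a median log2 fold of -1.70 over 8 measured genes (-1.92 to -1.47 with any 1 left out), while 7 of 11 supporting cell markers were higher and 2 lower (1.29) and all 14 mitochondrially encoded genes were higher (1.48). Pools, depth, the mix of clusters and wells mixed with supporting cells are each argued against as the whole cause, because the median was -1.25 within pool 1 (-1.30 to -1.21), -1.57 with every cell thinned (-1.68 to -1.45), -1.47 with clusters weighted as in wildtype (-1.70 to -1.25) and -1.61 without the wells that held at least 5 supporting cell markers (-1.69 to -1.52; 14.8% of Pou4f3-DTR and 5.06% of wildtype cells), past the 1.5-fold mark of 0.585 on the log2 scale in size each time. The Notch list, which shares 5 members with it, was at -1.07 within pool 1, -0.67 thinned and -0.46 weighted, but its reported median of -0.52 misses that mark itself, so these values do not decide. A higher mitochondrial share stays open, since only 5 Pou4f3-DTR cells lay under the median share of both groups (-2.82 there). Lower levels within the same clusters may be part of the pattern, as a hypothesis. Genotype, any treatment, the animals, the plates and the gates cannot be told apart as its source.

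Clusters 7, 8, 9 and 12 held 0 smartscribe cells. That 0 of 43 smartscribe cells at P2 lay in them was fixed by the choice of these clusters. The share of P2 maxima cells was not fixed, and 45.5% of them (15 of 33, 28.1 to 63.6%) lay in these clusters. As these cells shared pool, age and genotype with the P2 smartscribe cells, this share argues against pool, age and genotype as the whole cause. Depth may contribute: with every cell thinned and clustered again, 42.1% of maxima cells lay in clusters with under 5% smartscribe cells, against 53.3% before. The enzyme itself may contribute as well, since maxima to smartscribe folds at P2 and at P4, the latter mixed with pool and genotype, correlated across 3441 genes (Spearman's rho 0.37), although genes are not independent replicates. Transcript length was undecided, at a rho of 0.20 with the P2 folds over 4204 genes, within its spread of 0.0302 of the bound of 0.2; the use of that spread was decided after the value was seen.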
